A study of Homo sapiens with 25 samples.

How the data were processed

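The series measured messenger RNA in ZR-75.1 cells, an established estrogen receptor-positive human breast cancer line, after exposure to 17β-estradiol (E2), the main natural estrogen. Per the labels, cells were deprived of steroids before 50 nM E2 was added, and poly(A) RNA was taken at 11 times between 1 and 32 h. Each array compared the RNA of one time with RNA of hormone-deprived control cells on a spotted cDNA array, on which every probe is read in 2 dye channels. There were 25 arrays, 13 in the forward dye orientation (E2 sample in channel 2) and 12 with the dyes swapped.

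The deposited value table holds 9182 probes per array as log10 ratios of the 2 channels, and no spot intensity, background or quality mark was used here. The unit was read from the values: raised to the power of 10, 95.01% of the values were a ratio of whole numbers of modest size, against 0.72% of random values. Scanner, background correction and dye balancing are not given in the sources used here. The values were not centred between arrays, because the array medians ran from -0.044 to 0.512 on the log10 scale. Swapped arrays had not been turned, since forward and swapped arrays of the same time correlated negatively over all probes (Pearson r across probes from -0.45 to -0.07). A single value of -9.05, in the 32 h forward array, lies outside any scanner's range and was set to missing.

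The labels state which dye each RNA carried but not which channel was the numerator. The table was read as channel 1 over channel 2, so that forward arrays were turned, and the resulting direction of E2 over control is likely rather than settled. It rests on the whole numbers recovered from the ratios. In the forward arrays the recovered denominator followed the time profile measured in the swapped arrays (slope 0.285, 95% bootstrap interval 0.153 to 0.419, 500 probes), whereas the numerator did not (slope -0.028, interval -0.140 to 0.077). The same test in the swapped arrays gave no support. There the numerator should follow under this reading, but its slope was -0.0198 (interval -0.0882 to 0.0505), below that of the denominator (0.051, interval -0.015 to 0.119), and both intervals include 0. Textbook estrogen-induced genes such as TFF1 also came out higher under this reading. The direction was fixed after the values had been seen, the first reading had been the opposite one, and the slope test took its form after other versions. Under the opposite reading all signs turn together, while sizes, counts and p-values stay as they are. Between arrays of the same orientation r lay between 0.016 and 0.63 over 78 forward pairs and between -0.17 and 0.83 over 66 swapped pairs (median 0.31 and 0.50), and 5 swapped pairs were below 0. No array was turned for it, as none of these pairs was below a limit of -0.3.

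Values were converted to log2 ratios and each array was centred on its median. Without centring, the median of all features was 0.40 in the early window, 0.24 in the intermediate window and 0.18 in the late window, so every change is relative to the middle of the array. A platform annotation, with symbols brought up to date through a RefSeq gene table, gave 1 symbol for 7432 probes, several for 252 and none for 1498. Of the probes with 1 symbol, 20 kept the annotation's own symbol. Probes of one gene were averaged, which gave 6809 named genes (587 with more than 1 probe) and 1750 unnamed single probes, in all 8559 features.

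The labels state that the culture experiment was repeated and that hybridisations were repeated in separate experiments, in a description that breaks off there. They tie no array to a culture. Arrays of one time were therefore averaged within each orientation, and the 2 orientations were given equal weight. This cancels a dye effect that is alike on all arrays, but not one present on some arrays only: SLC26A3 changed by more than 1.5 on the log2 scale on 9 of 25 arrays, lower on 7 dye-swap arrays and higher on 2 forward arrays, the same dye direction each time. Means by orientation were computed after the values had been seen, and are given for a few genes with large gaps. The standard errors do not include that gap. The 11 time points were grouped into an early window (1, 2 and 4 h, n = 3), an intermediate window (6, 8 and 12 h, n = 3) and a late window (16, 20, 24, 28 and 32 h, n = 5). Time points were the units of the test and were treated as independent, although they are ordered in time. Each p-value measures the spread between time points within windows, pooled over the 3 windows and shrunk across features. An early p-value therefore also rests on the spread of the intermediate and late times. Part of that spread may be technical and part is change over time. Window means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 8 residual degrees of freedom before shrinkage). Benjamini-Hochberg adjustment ran over all features, with a threshold of 0.05. Each window was tested against 0 and the 3 windows against each other, 6 comparisons in all. The labels describe a common reference of hormone-deprived RNA, without stating that a single preparation served all times. A window against control was therefore treated as having 1 control sample, and leaves out the control's own spread. Differences between windows are free of the control only if the preparation was the same throughout. The number of arrays limits the precision: the median standard error was 0.081 for a window of 3 time points and 0.062 for the late window.

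Gene lists were fixed before the data were examined: estrogen-induced and estrogen-repressed genes, immediate-early genes, G1 regulators, DNA replication, mitosis, histones, ribosome biogenesis, ribosomal proteins, translation factors, tRNA synthetases, nucleotide synthesis, chaperones, folding in the endoplasmic reticulum, the proteasome, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, glycolysis, apoptosis, interferon response, growth factor signalling, luminal identity, markers of other cell types, housekeeping genes and stress genes. These 26 lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 104 tests in 4 comparisons. Genes named in the results follow a rule also fixed beforehand. For each window against control and for late minus early it takes the 10 largest rises and 10 largest falls among named genes past the threshold, with the same sign at every time point of the window or, for late minus early, no overlap between the windows. It also takes up to 4 members of each list with the largest change past the threshold. All measured estrogen-induced genes may be named. The design assumed a ratio table and needed no other test.

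The procedure was tested on simulated data with the measured spread of the 8559 features. Of 50 features changed by 0.5 on the log2 scale, 96% were recovered in the early window, 96% in the intermediate window, 98% in the late window and 88% in late minus early. At 0.25 the shares were 24%, 30%, 66% and 12%. Over all sizes 5, 12, 8 and 10 unchanged features were called. For the list test, the mitosis, chaperone and proteasome lists were shifted by 0.3 in the late window. All 6 resulting shifts, in the late window and in late minus early, were found, and no other list test was called. The simulated features varied independently, whereas the measured mitosis genes had an estimated correlation of 0.25. False list calls among correlated genes were therefore not measured. A further simulation without any changed gene let a control RNA shared by all arrays deviate like 1 time point. It gave on average 1429.5 calls in the early window, 1420.4 in the intermediate window and 2562.6 in the late window over 20 draws. In late minus early it gave 0. Counts against control cannot by themselves be told from a deviation of that size. The deviation was drawn from the whole spread between time points. That spread holds array noise and change over time, so it may exceed what a shared RNA would carry.

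Alternatives were other scalings (no centring, scaled arrays, quantile normalization), a single dye orientation, arrays as units, each probe on its own, robust shrinkage, other window limits, a minimum change of 1.2-fold, a linear trend, stricter and looser rules for missing values, camera with an estimated correlation, limma's fry, and leaving out each time point and each array. Chosen after seeing the data were loess on the recovered signal (span 0.3), leaving out the dimmest 25% of probes or the 6 arrays of lowest recovered signal (202 to 238, against 297 to 578 for the others), keeping the value of -9.05, and naming 28 h and the third 2 h array among the omissions. The recovered signal, from the whole numbers in the ratios, served only these alternatives, the direction and the tests of technical explanations. Background correction and a filter on spot quality could not be applied to ratios. Recovery and file handling used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.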

Results

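Transcript levels were followed in ZR-75.1 breast cancer cells over 32 h of E2 treatment, at 11 times and on 25 two-colour arrays, each against RNA from hormone-deprived control cells. There were 2 arrays at most times and 3 at 2, 8 and 16 h. Changes are log2 ratios of E2 over control with the standard error of the limma fit, relative to each array's median. The direction is likely but not settled, because the labels do not name the numerator. It rests on the channel signals recovered from the forward arrays, which the dye-swap arrays did not bear out, and on textbook estrogen-induced genes, was fixed after the values were seen, and would turn all signs together if wrong. Within a time point, the median standard deviation between arrays ran from 0.14 at 12 h to 0.22 at 28 h.

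TFF1, a secreted trefoil peptide and a classical estrogen target, moved from -0.14 at 1 h to 1.79 at 12 h and 2.73 at 28 h. STC2, a secreted glycoprotein hormone, stood at 0.88 after 1 h, 1.11 after 4 h and 0.43 after 28 h. Its 32 h value (0.19) averages -0.15 on the forward and 0.53 on the dye-swap array. Without a test at single times, mean changes of at least 2-fold in the same direction on every array were counted. They numbered 10 features at 1 h, 5 at 2 h, 14 at 4 h, 20 at 20 h, 74 at 28 h and 12 at 32 h. Without centring the counts at these times were 11, 42, 240, 119, 51 and 15. The largest then fell at 4 h, so the order of the times depends on centring. When the swapped arrays were deliberately left unturned, which measures dye and spot effects, 6, 1, 0, 0, 12 and 6 features reached that size at these times. The first principal component held 30.6% of the variance and ran from -12.7 at 1 h to 15.1 at 28 h. It did not follow time strictly, since 8 h (-5.28) lay below 6 h (-4.75), 24 h (6.09) below 16 h (6.90) and 20 h (9.83), and 32 h lay at 2.21. Each probe was also centred on its mean over all arrays of the same orientation. The 2 arrays of 32 h then differed from each other (r = -0.18 across probes), so that position is uncertain. The same r was 0.04 at 4 h, -0.03 at 6 h, 0.09 at 24 h and 0.05 at 28 h, and highest at 1 h (0.37). Positions of those 4 times with low r are therefore uncertain too. Most arrays correlated better with an array of another time than with one of their own time. Even at 1 h the best r with another time was 0.38 for the forward and 0.55 for the dye-swap array. Positions of the other times are thus not firmly set by their arrays either. At 28 h the forward array had a wider spread than its partner (standard deviation 0.55 against 0.28). The second component held 17.7% and set 28 h (14.3) apart from the rest.

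**Figure D1:**
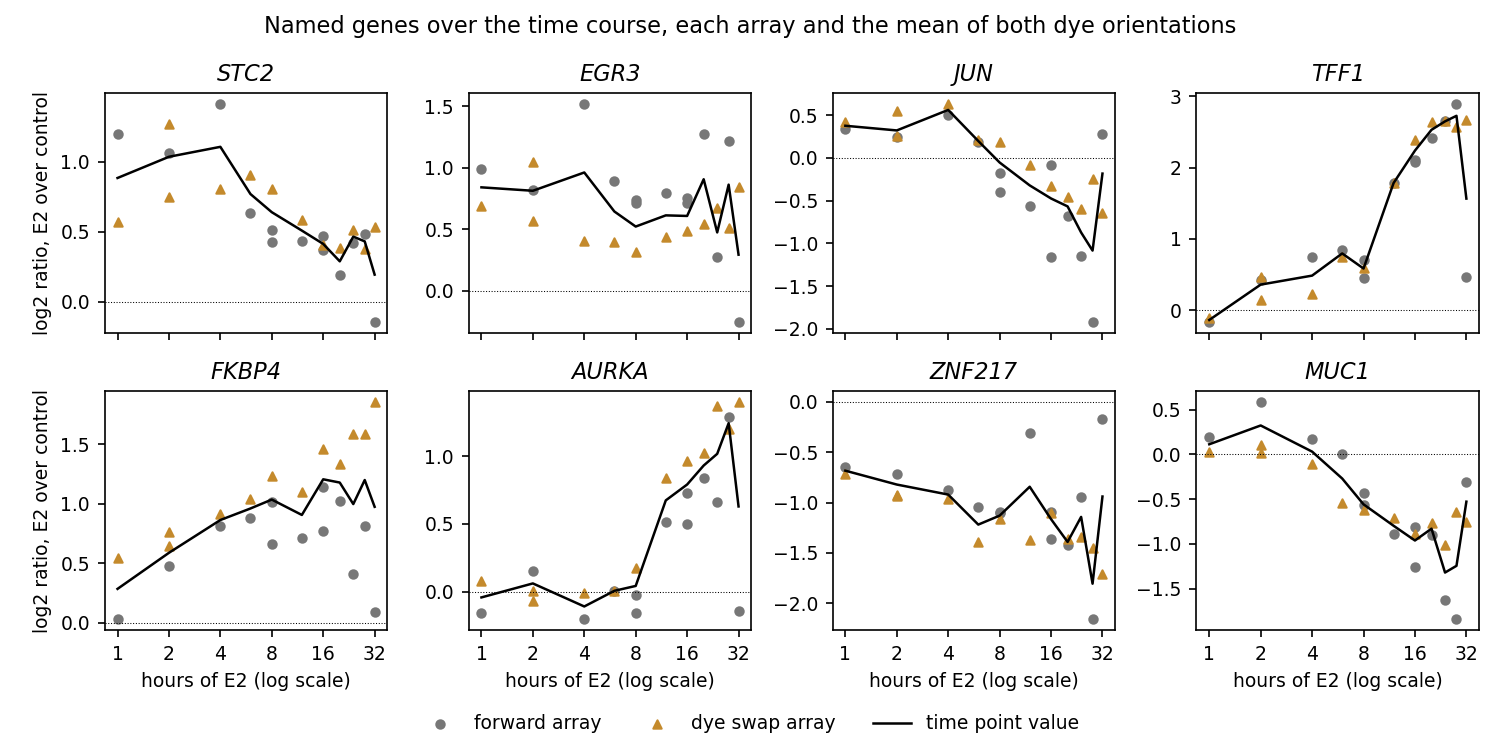
Log2 ratio of E2 over control for 8 named genes against hours of E2 on a log scale. Circles are forward arrays, triangles dye-swap arrays, and the line is the time point value. TFF1 reaches 2.73 at 28 h, and JUN passes from 0.56 at 4 h to -1.09 at 28 h.

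The first comparison asked what had changed within 4 h. STC2 rose by 1.01 ± 0.08 (SE, n = 3 time points, limma adjusted p = 1.2e-06). EGR3, an immediate-early zinc finger transcription factor, rose by 0.87 ± 0.10 (adjusted p = 9.5e-05 in limma). MYC, a transcription factor that drives growth, rose by 0.83 ± 0.10 (limma adjusted p = 0.00025) and CCND1, the cyclin that opens G1, by 0.74 ± 0.08 (limma adjusted p = 9.5e-05). IGFBP4, a binding protein of insulin-like growth factors, rose by 0.84 ± 0.11, CYP1A1, a cytochrome P450 enzyme and target of the aryl hydrocarbon receptor, by 0.91 ± 0.12, and SLC7A5, the light chain of an amino acid transporter, by 0.91 ± 0.18. KLF10, ZNF703 and EGR1, all transcriptional regulators, rose by 0.69, 0.69 and 0.66. ZNF217, a zinc finger oncogene product, fell by 0.81 ± 0.12 on the log2 scale (adjusted p = 0.00084 in limma).

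PPFIA3 (-0.85), CREBRF (-0.73) and RAB9B (-0.69) also fell early, and did so in forward arrays (-1.14, -0.83 and -0.62) and dye-swap arrays (-0.55, -0.62 and -0.76). The falls of 6 other genes past the threshold rested mainly on a single orientation. SLC26A3 (-1.05 ± 0.30) stood at -0.08 in forward and -2.02 in dye-swap arrays, and TYMS, which encodes thymidylate synthase (-0.73 ± 0.21), at -0.11 and -1.34. TOR1A (-0.79) stood at -1.75 in forward and 0.18 in dye-swap arrays, IFT122 (-0.78) at -1.41 and -0.15, ATP1B2 (-0.77) at -1.25 and -0.30, and XAB2 (-0.73) at -1.18 and -0.28. Of 90 early results of named genes, 16 had opposite signs in the 2 orientations or a smaller mean under 25% of the larger, against 3 of 83 in the intermediate and 7 of 111 in the late window. The spots of PPFIA3, ATP1B2 and XAB2 were among the dimmest of all, at recovered signal percentiles of 0.2, 0.3 and 0.2.

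Immediate-early genes rose as a group: 11 of 22 measured members were higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 0.30 and adjusted p = 6.2e-08 in camera, but adjusted p = 0.068 with an estimated correlation. Of 31 estrogen-induced genes, 8 were higher and 1 lower (12 and 2 adjusted over the list alone; adjusted p = 5.7e-05 in camera, adjusted p = 0.0961 with an estimated correlation). The list also served to judge the direction and is no independent evidence of it. Estrogen-repressed genes, used for the same purpose, did not fall in this window: 5 of 17 were higher and 3 lower (7 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.126 in camera, adjusted p = 0.318 with an estimated correlation). The lower gene among the estrogen-induced was PGR, the progesterone receptor (-0.42 ± 0.12, adjusted p = 0.034 in limma), from a spot at signal percentile 12.2. Ribosome biogenesis factors such as WDR43 (0.46), DKC1 (0.43) and NOLC1 (0.40) were higher in 11 of 34 and lower in 0 (13 and 0 adjusted over the list alone; adjusted p = 7.0e-05 in camera, adjusted p = 0.17 with an estimated correlation). Nucleotide synthesis had 3 of 19 higher, among them UMPS, of pyrimidine synthesis (0.47), and none lower (3 adjusted over the list alone; adjusted p = 0.0263 in camera, adjusted p = 0.0964 with an estimated correlation). Glycolysis had 3 of 15 higher, led by PFKFB3, which makes an activator of phosphofructokinase (0.52), and none lower (3 adjusted over the list alone; adjusted p = 0.0255 in camera, adjusted p = 0.0964 with an estimated correlation). Growth factor signalling had 7 of 44 higher and 1 lower, TGFB3 at -0.42 (10 and 2 adjusted over the list alone; adjusted p = 0.022 in camera, adjusted p = 0.255 with an estimated correlation). Ribosomal proteins shifted down by a median of -0.06, a direction that flips without centring, with RPL7 (-0.42) and RPLP1 (-0.27) the 2 called of 39 (1 adjusted over the list alone; adjusted p = 0.0441 in camera, adjusted p = 0.534 with an estimated correlation).

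In total 763 of 8559 features were higher and 522 lower in the early window, with a median size of 0.30, and 3 exceeded 2-fold. Without centring the share of higher calls was 99.7% in place of 59.4%. The falls lay at a median signal percentile of 14.9 and the rises at 70.6, and 340 of the 522 falls came from the dimmest 25% of features. The count of 1285 became 353, 391 and 235 without 1, 2 or 4 h, 559 without the first 4 h array, and 667, 400 and 334 without the second array of 20, 28 or 32 h. It was also below what a deviating control RNA gave in simulation (1343 to 1556 calls with no gene changed). Without the 6 arrays of lowest signal 237 features were called. Those 6 arrays, and the omitted arrays of 20, 28 and 32 h, lie outside the early window. Leaving them out kept the early means. These lower counts therefore came from the spread shared by all windows and not from smaller early changes.

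**Figure D2:**
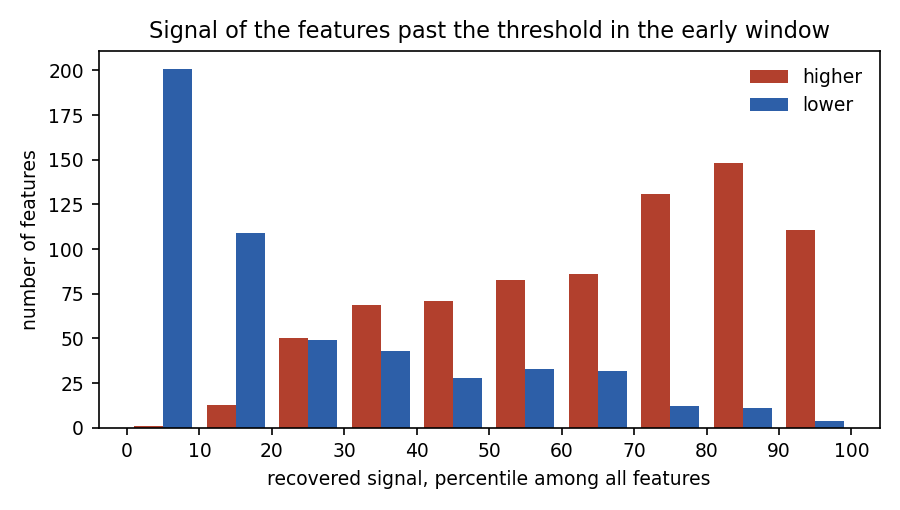
Number of features past the threshold in the early window against the percentile of their recovered signal among all features, in steps of 10 percentiles. Bars for features that were lower crowd at the dim end (median percentile 14.9) and bars for features that were higher at the bright end (median 70.6).

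Between 6 and 12 h, SLC7A5 and its partner SLC3A2, which together form an exchanger of large amino acids, rose by 1.17 ± 0.18 and 1.08 ± 0.09 (n = 3 time points, adjusted p = 0.00097 and 6.3e-06 in limma). TPD52L1, a coiled-coil protein, rose by 1.11 ± 0.13, TFF1 by 1.06 ± 0.20 and MKI67, the Ki-67 proliferation antigen, by 1.03 ± 0.23, the last from a spot at signal percentile 13.7. HSPA8, the constitutive Hsp70, rose by 0.99 ± 0.14 and FKBP4, a co-chaperone of steroid receptors, by 0.97 ± 0.09. HSPA5, the Hsp70 of the endoplasmic reticulum, rose by 0.85 ± 0.08, DKC1, the pseudouridine synthase of the nucleolus, by 0.87 ± 0.09, and SLC26A2, a sulfate transporter, by 0.84 ± 0.10. ZNF217 fell by 1.06 on the log2 scale, and ESR1, the estrogen receptor itself, fell by 0.65 ± 0.09 (adjusted p = 0.00022 in limma).

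CCNG2 (-0.81), HBP1 (-0.82) and BTG1 (-0.63), all known as brakes on proliferation, were lower, as were YPEL3 (-0.83), PLEKHF2 (-0.81), the ephrin EFNA1 (-0.72), TTC3 (-0.69) and the amino acid transporter SLC38A1 (-0.65). Of 17 estrogen-repressed genes, also used to judge the direction, 5 were lower and none higher (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00328 in camera, adjusted p = 0.0995 with an estimated correlation). Their median of -0.05 turned without centring and in the forward arrays alone. Luminal identity genes were lower in 4 of 20, namely ESR1, MUC1 (-0.54), CLDN4 (-0.50) and FOXA1 (-0.31), and higher in none (7 and 0 adjusted over the list alone; adjusted p = 0.000234 in camera, adjusted p = 0.0706 with an estimated correlation). Their median of -0.10 turned without centring.

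Chaperones had 12 of 30 higher and 0 lower (16 and 1 adjusted over the list alone; adjusted p = 4.2e-07 in camera, adjusted p = 0.0964 with an estimated correlation), with FKBP5 at 0.69 and STIP1 at 0.60. Ribosome biogenesis had 13 of 34 higher and 0 lower (17 and 0 adjusted over the list alone; adjusted p = 1.5e-07 in camera, adjusted p = 0.0964 with an estimated correlation), with NOLC1 at 0.79 and NOP56 at 0.57. Aminoacyl-tRNA synthetases had 6 of 16 higher and 0 lower, led by YARS1 (0.56) and VARS1 (0.48) (8 and 0 adjusted over the list alone; adjusted p = 5.4e-05 in camera, adjusted p = 0.0961 with an estimated correlation). DNA replication had 7 of 42 higher and 0 lower, led by the flap endonuclease FEN1 (0.53) and the helicase subunits MCM7 (0.52) and MCM2 (0.46) (11 and 2 adjusted over the list alone; adjusted p = 9.5e-05 in camera, adjusted p = 0.0995 with an estimated correlation). Estrogen-induced genes had 13 of 31 higher and 0 lower (16 and 2 adjusted over the list alone; adjusted p = 5.4e-07 in camera, adjusted p = 0.0706 with an estimated correlation).

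Camera also called nucleotide synthesis upward, with 6 of 19 higher (adjusted p = 0.00136, adjusted p = 0.0706 with an estimated correlation). Immediate-early genes had 4 of 22 higher (adjusted p = 0.00552, adjusted p = 0.104 with an estimated correlation). Translation factors had 4 of 29 higher (adjusted p = 0.0103, adjusted p = 0.199 with an estimated correlation). Mitosis had 5 of 53 higher, MKI67 among them (adjusted p = 0.0134, adjusted p = 0.505 with an estimated correlation). Glycolysis had 2 of 15 higher and 1 lower (adjusted p = 0.0394, adjusted p = 0.104 with an estimated correlation). Adjusted over the list alone, 8, 6, 6, 9 and 5 of their members were higher. The lower glycolytic gene was the enolase ENO1 (-0.38). No ribosomal protein of 39 was called (0 adjusted over the list alone), yet camera placed the list downward (median -0.07; adjusted p = 0.0112, adjusted p = 0.454 with an estimated correlation), a direction that flips without centring, with loess and in the forward arrays alone.

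In this window 455 features were higher and 288 lower, with a median size of 0.32. The share of higher calls was 61.2%, against 99.1% without centring and 47.3% after quantile normalization. The count of 743 became 198, 222 and 305 without 6, 8 or 12 h, 428, 315, 400, 211 and 169 without the second array of 4, 20, 24, 28 or 32 h, and 427 without the third 16 h array. These single arrays lie outside the window, so leaving them out changed only the spread shared by all windows. The count of 743 was below the 1344 to 1490 calls that a deviating control RNA gave in simulation, and the forward arrays alone gave 20.

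From 16 h on, TFF1 stood highest at 2.34 ± 0.16 (n = 5 time points, adjusted p = 2.7e-08 in limma). FKBP4 rose by 1.11 ± 0.07, SLC3A2 by 1.06 ± 0.07, TPD52L1 by 1.04 ± 0.10 and SERPINA3, a secreted protease inhibitor, by 1.03 ± 0.08. CCT5, a subunit of the cytosolic chaperonin, rose by 0.90 ± 0.07, the transcription factor MYB by 0.90 ± 0.07 and SLC7A5 by 0.85 ± 0.14. Several of these rises were larger in dye-swap than in forward arrays: 1.56 against 0.66 for FKBP4, 1.45 against 0.60 for SERPINA3 and 1.18 against 0.62 for MYB. The mitotic kinase AURKA and the mitotic kinesin KIF20A rose by 0.92 ± 0.09 and 0.87 ± 0.08 (adjusted p = 1.1e-06 and 1.0e-06 in limma), KIF20A by 1.19 in dye-swap and 0.55 in forward arrays. ZNF217 fell by 1.29 ± 0.09 on the log2 scale, the protease inhibitor CSTA by 1.10, acetylcholinesterase (ACHE) by 1.05 ± 0.07 and the mucin MUC1 by 0.98 ± 0.09. On the same scale the immune checkpoint ligand VTCN1 fell by 0.97, the ecto-nucleotidase NT5E by 0.91, the interferon-inducible IFI6 by 0.89 ± 0.08, SYTL2 by 0.86, PGM5 by 0.86 and BTG1 by 0.82. The SYTL2 change at 32 h (-0.38) was smaller than at the other late times.

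Genes of mitosis rose as a group: 39 of 53 were higher and 2 lower (40 and 3 adjusted over the list alone), with a median of 0.45 (adjusted p = 8.9e-15 in camera, adjusted p = 0.0964 with an estimated correlation). Its median was -0.005 at 8 h and 0.33 at 12 h. DNA replication had 25 of 42 higher and 3 lower (25 and 3 adjusted over the list alone; adjusted p = 7.1e-06 in camera, adjusted p = 0.0961 with an estimated correlation). It was led by MCM7 (0.81), whose 2 probes gave 0.49 and 1.13, thymidine kinase TK1 (0.75) and the dUTPase DUT (0.72). G1 regulators had 11 of 24 higher, among them CCND1 (0.56) and CDK2 (0.42), and 4 lower, CCNG2 at -0.73 among them (12 and 4 adjusted over the list alone; adjusted p = 0.00962 in camera, adjusted p = 0.0961 with an estimated correlation). Nucleotide synthesis had 10 of 19 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 2.4e-05 in camera, adjusted p = 0.068 with an estimated correlation), led by the folate enzyme MTHFD1 (0.85) and the purine enzyme PAICS (0.70).

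**Figure D3:**
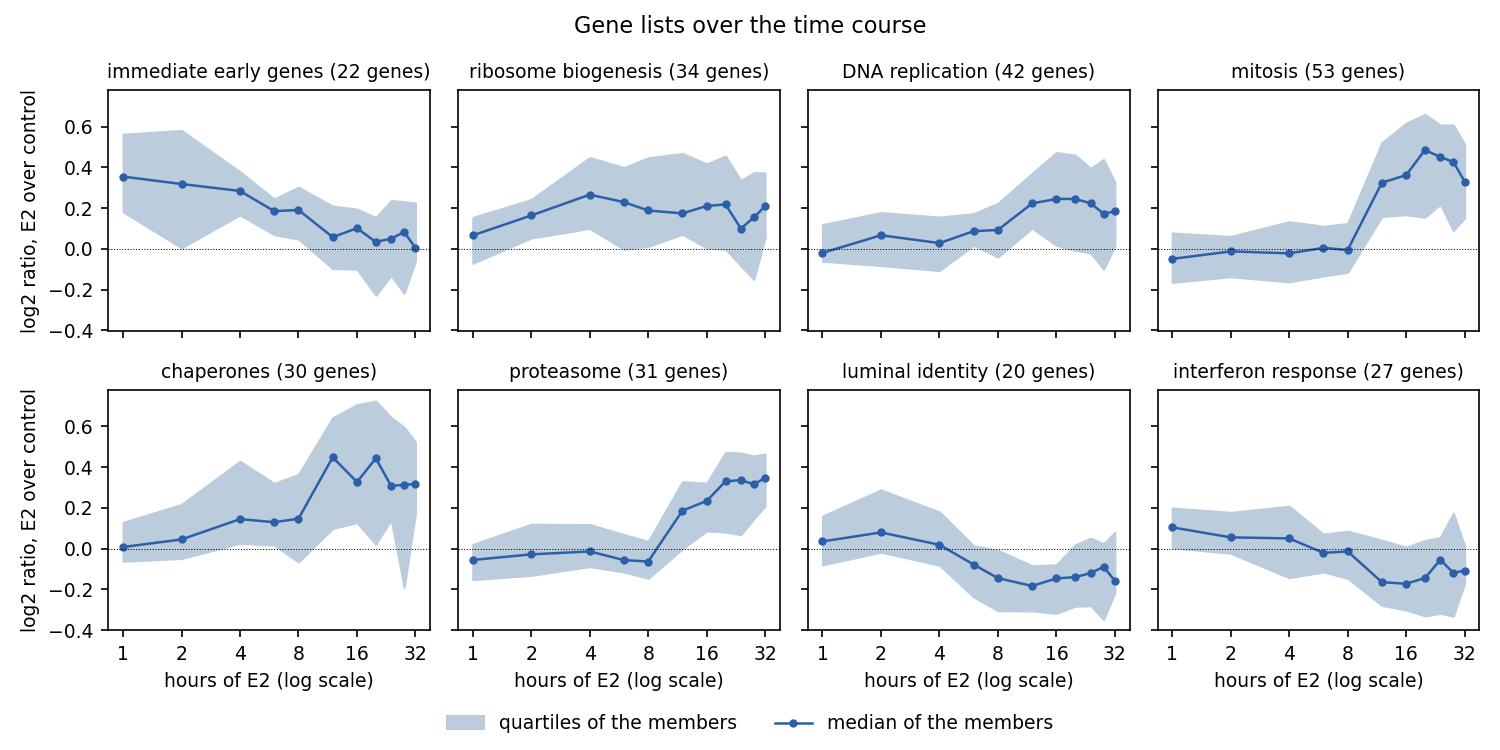
Median log2 ratio of E2 over control over the measured members of 8 gene lists (line) with their quartiles (shading), against hours of E2 on a log scale. The medians of mitosis and the proteasome are near or below 0 until 8 h and reach 0.49 and 0.33 at 20 h, while that of immediate-early genes is highest at 1 h (0.36). The medians of luminal identity and interferon response turn below 0, a direction that flips against control without centring.

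Protein folding and turnover rose in the same hours. Chaperones had 19 of 30 higher and 2 lower (20 and 2 adjusted over the list alone; median 0.43, adjusted p = 1.5e-07 in camera, adjusted p = 0.0964 with an estimated correlation). Folding factors of the endoplasmic reticulum had 20 of 36 higher and 1 lower, HSPA5 at 0.64 and HSP90B1 at 0.57 among the former (21 and 1 adjusted over the list alone; adjusted p = 4.2e-06 in camera, adjusted p = 0.0964 with an estimated correlation). Proteasome subunits had 22 of 31 higher and 2 lower, with PSMD11 at 0.68 and PSMB6 at 0.61 (22 and 3 adjusted over the list alone; adjusted p = 5.4e-07 in camera, adjusted p = 0.0964 with an estimated correlation). Ribosomal proteins had 18 of 39 higher and 1 lower, with RPL7A at 0.36 (20 and 1 adjusted over the list alone; adjusted p = 7.4e-05 in camera, adjusted p = 0.26 with an estimated correlation). Ribosome biogenesis had 17 of 34 higher and 4 lower (18 and 5 adjusted over the list alone; adjusted p = 0.000828 in camera, adjusted p = 0.238 with an estimated correlation). Translation factors had 15 of 29 higher and 2 lower (16 and 2 adjusted over the list alone; adjusted p = 0.000489 in camera, adjusted p = 0.102 with an estimated correlation). Of the tRNA synthetases, 8 of 16 were higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 5.4e-05 in camera, adjusted p = 0.0961 with an estimated correlation).

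Of the metabolic lists, fatty acid synthesis was not called against control (3 of 8 higher and 1 lower, median 0.04; adjusted p = 0.187 in camera, adjusted p = 0.286 with an estimated correlation), whereas 3 others shifted upward. Oxidative phosphorylation had 22 of 52 higher and 3 lower, with COX6C at 0.53 (23 and 3 adjusted over the list alone; adjusted p = 0.000335 in camera, adjusted p = 0.255 with an estimated correlation). Cholesterol synthesis had 8 of 16 higher and 2 lower, with farnesyl diphosphate synthase FDPS at 0.70 and squalene epoxidase SQLE at 0.53 (8 and 2 adjusted over the list alone; adjusted p = 0.0247 in camera, adjusted p = 0.0964 with an estimated correlation). Glycolysis had 9 of 15 higher, pyruvate kinase PKM at 0.60 among them, and 1 lower, ENO1 at -0.39 (9 and 1 adjusted over the list alone; adjusted p = 0.011 in camera, adjusted p = 0.0961 with an estimated correlation).

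Estrogen-induced genes had 18 of 31 higher and 2 lower (18 and 3 adjusted over the list alone; adjusted p = 6.1e-07 in camera, adjusted p = 0.0706 with an estimated correlation). Among the former were the lysosomal protease CTSD (0.66), the scaffold PDZK1 (0.67) and BCL2, which blocks apoptosis (0.43). The 2 lower ones were GREB1 (-0.21 ± 0.06, adjusted p = 0.015 in limma), elsewhere known as an estrogen-induced gene, and TRIM25 (-0.17). Estrogen-repressed genes were lower in 8 of 17 and higher in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.0134 in camera, adjusted p = 0.138 with an estimated correlation). Interferon-responsive genes were lower in 12 of 27 and higher in 1 (13 and 2 adjusted over the list alone; adjusted p = 0.0222 in camera, adjusted p = 0.238 with an estimated correlation). Luminal identity genes were lower in 9 of 20 and higher in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.0263 in camera, adjusted p = 0.104 with an estimated correlation). The medians of these 3 lists, -0.11, -0.11 and -0.13, turned without centring.

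Of all features, 1491 were higher and 1620 lower in the late window, with a median size of 0.27, and 11 exceeded 2-fold. The share of higher calls was 47.9%, against 92.3% without centring. The count of 3111 became 2005 without the second 32 h array and 1233 in the forward arrays alone, and a deviating control RNA gave 2486 to 2685 calls in simulation with no gene changed.

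**Figure D4:**
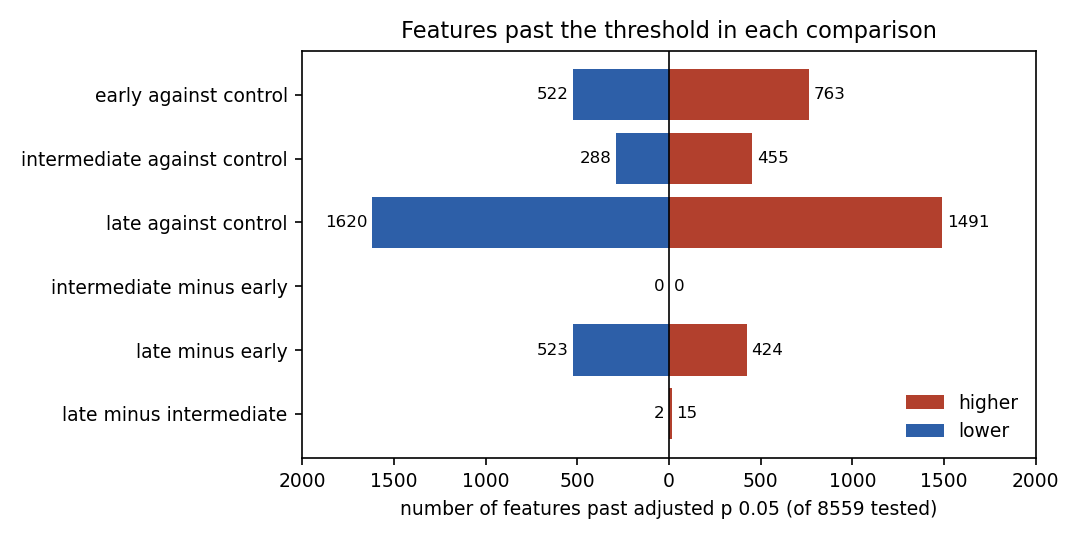
Number of features past an adjusted p of 0.05 in each of the 6 comparisons, with higher features to the right and lower ones to the left of 0. The late window has the most (1491 and 1620), late minus early has 424 and 523, and intermediate minus early has none.

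Whether responses differed between early and late times was tested on the difference of the windows, from which a control RNA common to all arrays drops out. Against such a common control, hours of E2 and hours in culture run together. An effect of E2 on these differences therefore cannot be told apart from change with time in culture. TFF1 was 2.11 ± 0.25 higher late than early (5 and 3 time points, adjusted p = 0.00024 in limma). KIF20A (1.00 ± 0.14), AURKA (0.95 ± 0.15), the PCNA-binding factor PCLAF (0.94), the histone variant H2AZ1 (0.91), the spindle factor DLGAP5 (0.89), SERPINA3 (0.87), the exonuclease EXO1 (0.82), CCT5 (0.82) and the cytokinesis regulator RACGAP1 (0.81) followed. Lower late than early were IFI6 (-1.15 ± 0.13, adjusted p = 0.00024 in limma), MUC1 (-1.13 ± 0.15), ACHE (-1.09 ± 0.11) and JUN, a subunit of the AP-1 transcription factor (-1.06 ± 0.16). So were PGM5 (-1.02), EGR1 (-0.94 ± 0.12), CYP1A1 (-0.93), ANXA9 (-0.86), NT5E (-0.81) and CSTA (-0.79). ANXA9 owed part of its difference to 28 h, where it stood at -1.18.

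Mitosis genes were higher late in 31 of 53 and lower in 1 (37 and 2 adjusted over the list alone; median 0.38, adjusted p = 2.9e-20 in camera, adjusted p = 0.0961 with an estimated correlation). DNA replication was higher in 10 of 42 and lower in none (16 and 1 adjusted over the list alone; adjusted p = 1.2e-05 in camera, adjusted p = 0.0964 with an estimated correlation), with DUT at 0.78 and TK1 at 0.74. Proteasome subunits were higher in 13 of 31 and lower in none (18 and 3 adjusted over the list alone; adjusted p = 1.1e-07 in camera, adjusted p = 0.0964 with an estimated correlation), with PSMD11 at 0.79. Chaperones were higher in 10 of 30 and lower in 1, the co-chaperone BAG1 at -0.63 (13 and 1 adjusted over the list alone; adjusted p = 1.5e-06 in camera, adjusted p = 0.0995 with an estimated correlation). Without centring the medians shrank from 0.38 to 0.18 for mitosis and from 0.22 to 0.01 for DNA replication. Those of the proteasome and chaperones shrank from 0.33 to 0.12 and from 0.31 to 0.10. Ribosomal proteins, whose median of 0.23 was 0.02 without centring, were higher in 8 of 39 and lower in none (14 and 0 adjusted over the list alone; adjusted p = 1.1e-07 in camera, adjusted p = 0.138 with an estimated correlation).

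Immediate-early genes were lower late in 8 of 22 and higher in none (9 and 0 adjusted over the list alone; median -0.26, adjusted p = 7.1e-06 in camera, adjusted p = 0.0706 with an estimated correlation), JUN, EGR1, NR4A1 (-0.53) and MYC (-0.53) among them. Estrogen-repressed genes were lower in 7 of 17 (7 adjusted over the list alone; adjusted p = 1.2e-05 in camera, adjusted p = 0.0706 with an estimated correlation), with the transcriptional regulator CITED2 at -0.74. Interferon-responsive genes were lower in 5 of 27 (9 adjusted over the list alone; adjusted p = 9.9e-05 in camera, adjusted p = 0.0964 with an estimated correlation). Luminal identity genes were lower in 6 of 20 and higher in 1, the secreted AGR2 at 0.74, whose late value was 0.17 in forward and 0.78 in dye-swap arrays (7 and 1 adjusted over the list alone; adjusted p = 0.000828 in camera, adjusted p = 0.0804 with an estimated correlation). Growth factor signalling was lower in 9 of 44 (9 adjusted over the list alone; adjusted p = 0.0251 in camera, adjusted p = 0.26 with an estimated correlation), with the receptor ERBB3 at -0.64.

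A further group of lists was called upward with a direction that flips without centring. Endoplasmic reticulum folding had 9 of 36 higher late (11 adjusted over the list alone; adjusted p = 1.0e-05 in camera, adjusted p = 0.0964 with an estimated correlation). Oxidative phosphorylation had 12 of 52 (12 adjusted over the list alone; adjusted p = 1.2e-05 in camera, adjusted p = 0.176 with an estimated correlation). For tRNA synthetases it was 4 of 16 (7 adjusted over the list alone; adjusted p = 0.00196 in camera, adjusted p = 0.104 with an estimated correlation). Nucleotide synthesis, which also flips in the forward arrays alone, had 4 of 19 (5 adjusted over the list alone; adjusted p = 0.00482 in camera, adjusted p = 0.0951 with an estimated correlation). Cholesterol synthesis had 4 of 16 (4 adjusted over the list alone; adjusted p = 0.0357 in camera, adjusted p = 0.102 with an estimated correlation). Fatty acid synthesis had 2 of 8, the malic enzyme ME1 at 0.64 and ATP citrate lyase ACLY at 0.49 (2 adjusted over the list alone; adjusted p = 0.0247 in camera, adjusted p = 0.102 with an estimated correlation). None of these 6 lists had a lower member.

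Late minus early called 424 features higher and 523 lower, with a median size of 0.41. The share of higher calls was 44.8%, against 4.1% without centring, where the median of all features was -0.21, and 60.6% with loess on the recovered signal. The count of 947 became 300, 356 and 594 without 1, 2 or 4 h and 583, 291 and 236 without the second array of 20, 28 or 32 h. The forward arrays alone gave 81 and the fit without the 6 arrays of lowest signal 281.

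Of the neighbouring windows, late minus intermediate called 15 features higher and 2 lower. TFF1 (1.29 ± 0.25, adjusted p = 0.0473 in limma), KIF20A (0.90), MTHFD1 (0.60), TK1 (0.52) and the metallothionein MT1X (0.49) were higher and NT5E (-0.51) lower. The count ranged from 0 to 176 when single time points or arrays were left out. It was 0 without 6, 8, 20 or 24 h or the second array of 28 or 32 h, 111 without 12 h, 60 without 32 h and 176 without the first 32 h array. Intermediate minus early called 0 features in limma, while 1083 passed an unadjusted p of 0.05, and robust shrinkage also gave 0. Without 28 h it called 33, without the first 28 h array 29, without 4 h 15 and without the second 4 h array 6.

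Lists that camera called in none of the 4 comparisons were histones, apoptosis, markers of other cell types, housekeeping genes and stress genes. In the late window H1-3 (-0.48) was among 5 lower and H2AX (0.44; 0.05 in forward and 0.84 in dye-swap arrays) among 3 higher of 13 histone genes (3 higher and 5 lower adjusted over the list alone; adjusted p = 0.822 in camera). Only these 13 of 60 listed histone genes were measured, in poly(A) RNA, so the result says little about histone genes as a whole. BAK1, which promotes apoptosis, stood at -0.68 among 9 lower and 6 higher of 33 apoptosis genes (7 higher and 10 lower adjusted over the list alone; adjusted p = 0.218 in camera). Markers of other cell types had 5 of 28 higher, FN1 at 0.40 among them, and 4 lower, KRT5 at -0.33 among them (4 and 4 adjusted over the list alone; adjusted p = 0.989 in camera). Of 9 housekeeping genes TUBB (0.45) was among 5 higher and GUSB (-0.48) among 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.134 in camera). Their median of 0.24 exceeded that of some lists called upward, such as ribosomal proteins (0.17) and oxidative phosphorylation (0.14). Of 15 stress genes MT1X (0.67) was among 4 higher and NQO1 (-0.57) among 4 lower (4 and 4 adjusted over the list alone; adjusted p = 0.988 in camera).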

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

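The tests of explanations below were set down before their results were seen, but the recovered signal that some of them use was introduced after the values had been examined. The test that held out 1 h was chosen after the results were seen. Changes are log2 ratios of E2 over control, and their direction is not settled.

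Of 155 named genes and 26 list medians, 12 genes and 2 lists had a late time point far from the other 4 by Dixon's test, where chance picks about 1 in 20. At 32 h SYTL2 stood at -0.38 (nearest other time -0.92), CITED2 at -0.46 (-0.66), FKBP5 at 1.09 (0.83), HSP90B1 at 0.058 (0.62) and IFITM1 at -0.14 (-0.28). At 28 h ANXA9 stood at -1.18 (-0.61), ACLY at 0.72 (0.39) and AIMP1 at -0.36 (0.15). At 16, 20 and 24 h the distant values were HSPA8 at 1.08 (0.82), HSPA5 at 0.84 (0.63), OXSM at -0.67 (-0.29) and RPA3 at 0.81 (0.57). The chaperone median was highest at 20 h (0.44, nearest 0.33) and the proteasome median lowest at 16 h (0.23, nearest 0.32).

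Some results went in opposite directions early and late, with the difference itself past the threshold in limma. For a gene called in both windows the difference adds both sizes, so it passes nearly by construction. JUN passed from 0.42 to -0.64 (difference -1.06), EGR1 from 0.66 to -0.28 (-0.94) and TGFB2, a growth-inhibiting cytokine, from 0.34 to -0.35 (-0.69). The mitotic kinase MELK passed from -0.31 to 0.49 (0.80), although its early value was 0.08 without centring. The median of ribosomal proteins passed from -0.06, which flips without centring, to 0.17, and its late minus early median was 0.23, or 0.02 without centring (adjusted p = 1.1e-07 in camera, adjusted p = 0.138 with an estimated correlation).

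Other splits of the time points bear on the counts between windows. For late minus early, only the real split of 56 reached 947 features, and the highest other gave 12. A grouping unrelated to the order of the times is argued against. Because the times are ordered, a gradual change of any cause would also favour the real split, and the splits cannot exclude it. For late minus intermediate, 3 of 56 splits, the real one included, gave at least 17 features, so chance cannot be excluded. The highest other split, which set 20, 24 and 28 h against the rest, gave 97 and points to a structure of the samples, whose cause was not tested. For intermediate minus early, with 0 real calls and 1 in the highest other split, the 10 splits are too few for a share under 0.05.

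The first pattern weighed was the fall of 522 features within 4 h. The third 2 h array, a dye swap, had r = -0.014 with the other 2 h dye swap over all probes as deposited. With the 2 h forward array its r was -0.24, the sign of agreement once swaps are turned. The third array is argued against as the whole cause, because 398 of the 522 falls (76.2%) were still called without it. Dim spots stay open as a source: the falls had a median signal percentile of 14.9, against 70.6 for the rises, and loess on the recovered signal left 283 falls in place of 522. A true early loss of weakly expressed transcripts also stays open, since low expression and dim spots could not be told apart here. The same trend with signal may have raised part of the 763 rises, since loess left 535.

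The late rise of mitosis, chaperone and proteasome genes was weighed next. A bias alike for all genes of the same signal is argued against, because the 3 medians (0.45, 0.43 and 0.30) lay above the 95th percentile of 10000 random lists matched on signal (0.05, 0.08 and 0.08), by at least 0.22. Other lists passed this bar too, among them housekeeping genes (median 0.24, 95th percentile 0.14), so it does not mark out these 3. The 28 h time point alone is argued against too, since the medians kept at least 91.7% of their size without it. A candidate explanation, and no more than a hypothesis, is that E2 took cells resting in hormone-free medium into the cell cycle, with folding and turnover of proteins rising alongside. No cell-cycle entry was measured. DNA content of the same cultures would bear on entry into the cycle, but not on E2 as its cause or on folding and turnover. With an estimated correlation in camera none of the 3 lists was called (adjusted p = 0.0964 for each).

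The third pattern was a set of 223 features called in the same direction in all 3 windows, 171 higher and 52 lower, ZNF217, CCND1 and FKBP4 among them. Independent lists would share 7.1 and 3.3, while a simulated deviation of a control RNA shared by all arrays with no gene changed gave 632.2 on average (587 to 689 over 20 draws). That deviation had the size of the spread between time points, which may be too large for a control RNA. The median ratio of the 1 h shift to the mean later shift was 0.857 (quartiles 0.573 to 1.18), which decides little, since 1 h helped to choose these features. Among 106 features chosen without 1 h it was 0.756 (quartiles 0.395 to 1.159), between the bounds of 0.8 for a deviating control and 0.5 against it. A deviation of the control and a fast, lasting response to E2 both stay open, and whether 1 preparation served all times is not stated in the labels.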

How the results depend on the processing

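Tests chosen after the data were seen were loess on the recovered signal, leaving out the dimmest 25% of probes, leaving out the 6 arrays of lowest signal, keeping the value of -9.05, and singling out 28 h and the third 2 h array among those left out. Counts are features past the threshold, first with the planned setting and then with the alternative, and the cause was not tested unless stated. No paired analysis was possible because the replicate numbers only order the arrays of a time and pair nothing. Background correction and a filter on spot quality were not run, as ratios hold neither. The rules for missing values, with 1 value missing, and robust shrinkage moved no count by over 1.5 times, nor did keeping -9.05 or a linear trend for late minus early (723 against 947).

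For the early window (1285), no centring gave 6397, dye-swap arrays alone 700, windows of 1 to 2, 4 to 8 and 12 to 32 h 232, a minimum change of 1.2-fold 12, loess 818 (535 higher, 283 lower), the dimmest 25% left out 782 (514 higher, 268 lower) and the 6 dim arrays left out 237. None of these 6 arrays is from the early window, so there only the spread shared by all windows changed. For the intermediate window (743), no centring gave 2470, scaled arrays 1531, quantile normalization 1712, forward arrays alone 20, dye-swap arrays alone 1895, 1.2-fold 30 and the 6 arrays left out 410. For the late window (3111), forward arrays alone gave 1233 and 1.2-fold 311. The 1.2-fold setting asks for more than the main test by construction, and single orientations use fewer arrays and keep the dye effect.

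For late minus early (947), forward arrays alone gave 81, the windows of 1 to 2, 4 to 8 and 12 to 32 h 574, those of 1 to 6, 8 to 16 and 20 to 32 h 541, 1.2-fold 36 and the 6 arrays left out 281. For intermediate minus early (0 in limma, 1083 at an unadjusted p of 0.05), no centring gave 8, scaled arrays 27, quantile normalization 44, arrays as units 29, dye-swap arrays alone 13, the first other windows 7 and the 6 arrays left out 1. For late minus intermediate (17), no centring and quantile normalization gave 4 each, arrays as units 116, dye-swap arrays alone 209, each probe on its own 3, the first other windows 256, loess 45 and the dimmest 25% left out 60. It gave 0 in forward arrays alone, with the second other windows, at 1.2-fold and without the 6 arrays, all with limma, against 1186 at an unadjusted p of 0.05 in the planned fit.

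Of the gene lists, 7 were called early, 13 in the intermediate window, 18 late and 16 in late minus early. With an estimated correlation camera called 0 in each of the 4. Limma's fry, which asks only whether a list's genes move one way, called 13 early. With loess or without the dimmest 25% of probes, 5 of the 7 early calls were kept in each case and 2 others entered, nucleotide synthesis and glycolysis being lost (adjusted p = 0.15 and 0.112 with loess in camera). Forward arrays alone gave 4 early, 8 intermediate and 9 in late minus early.

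When single time points or arrays were left out, the counts ranged from 235 to 1783 early, 169 to 1110 intermediate, 2005 to 3800 late, 0 to 33 in intermediate minus early, 236 to 1147 in late minus early and 0 to 176 in late minus intermediate. For the gene lists, where only time points were left out, counts ranged from 6 to 7, 11 to 17, 16 to 18 and 14 to 18 in the order above. Leaving out 1 of 3 early or intermediate time points leaves 2 in that window, so those tests rest on fewer time points by construction. The second 32 h array, a dye swap, gave the lowest counts in the intermediate window (169), the late window (2005) and late minus early (236), after which only the forward array stood for that time. The intermediate means do not depend on that array, so there only the spread shared by all windows changed.

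Of 381 results of named genes, 252 kept direction and side of the threshold without the 6 arrays, 115 at 1.2-fold, 143 in forward arrays, 318 in dye-swap arrays, 296 without centring, 338 with loess, 367 with quantile normalization, 245 without the second 28 h array and 227 without the second 32 h array. Directions turned for 17 results. In dye-swap arrays alone the early values were TOR1A 0.18, PLK1 -0.0425 and IRF7 -0.0469, and in forward arrays alone ISG20 was -0.0419. Loess gave GCLM 0.056 in late minus early. Without centring the early values became MELK 0.0797, TTK 0.0908, H2BC12 0.0846, RPLP1 0.13, IARS2 0.0034, CALU 0.0908, GGPS1 0.15, OXSM 0.0241, IFIT2 0.10, LUM 0.0582 and SESN1 0.0167, and the intermediate value of H2AC17 became 0.0169. Leaving out centring adds the same amount to all features of a window, so small falls turn by construction.

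Signal over background cannot be judged from ratios, and the recovered signal stands in for it here. The dimmest spots carried 65.1% of the early falls, against 14.6% of those in the intermediate window and 18.4% of those in the late window. A split of the time points into 2 sets, first noticed in measured values, was also tried once as a block outside these settings. Its counts are not reported as a result because the sets were picked from the outcome.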

Other observations

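Besides JUN and EGR1, further features changed direction over time. In all, 32 features were called in opposite directions early and late. For each the difference was also past the threshold in limma. That follows nearly by construction from the calls, since the difference adds the sizes of both windows, and is no further support. Of the 32 features, 18 were higher early and lower late, and 14 the reverse. In 23 of the 32 both signs were the same in forward and in dye-swap arrays, the genes below included. The following were chosen after their values were seen. GDF15, a stress-induced cytokine, passed from 0.29 to -0.41 (difference -0.70, adjusted p = 0.00101 in limma) and the transcription factor CUX1 from 0.37 to -0.39 (-0.76). In the other direction, EED, a subunit of the Polycomb complex, passed from -0.29 to 0.43 (0.72, adjusted p = 0.000926 in limma) and the checkpoint kinase CHEK1 from -0.21 to 0.16 (0.37). All these values are relative to the array median. Leaving out centring adds the same amount to all features of a window, and small early falls then turn by construction (EED 0.10, CHEK1 0.19). The named genes among the 14 then all had positive early values. Of the 14, only GSTO2, MELK and EED kept a difference past the threshold without centring (adjusted p = 0.0116, 0.0119 and 0.0315 in limma). CHEK1 was among those that lost it (adjusted p = 0.521 in limma), while the 18 that were higher early all kept it.

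The array of 32 h in the forward orientation lay apart from its partner. TFF1 was 0.47 on it and 2.66 on the dye swap of the same time, AURKA -0.14 and 1.40, and FKBP4 0.09 and 1.86, where both arrays of 28 h gave TFF1 values of 2.89 and 2.57. It also holds the value of -9.05. After each probe was centred on its mean over all arrays of the same orientation, this array and its partner correlated at r = -0.18. That r runs across probes, which are not independent replicates. Without this array the late window had 3800 calls in place of 3111 and late minus early 1147 in place of 947.

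A low reading of SLC26A3 and TYMS at 1, 2, 8, 16, 24 and 32 h was a dye effect of some arrays. SLC26A3 read between -3.18 and -2.72 on the dye swaps of these times but 2.75 and 3.02 on the first forward arrays of 8 and 16 h, which is the same dye direction, and near 0 on most others. TYMS exceeded 1.5 on the log2 scale on 9 of 25 arrays in the same manner (7 dye swaps lower, 2 forward arrays higher). The early falls of these genes are therefore no evidence of a response to E2. An informal scan of splits of the time points, made after these profiles were seen, ranked this order of times first, and no p-value is given because the sets were picked from the values.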
